A study of Homo sapiens with 26 samples.

How the data were processed

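Poly(A) RNA was sequenced from 26 libraries of 786-O, a human clear cell renal carcinoma line that lacks functional VHL and so keeps the transcription factor HIF-2 active. Per the labels, siRNAs were transfected with DharmaFECT 1, cells were split 24 h later and harvested 48 h after transfection, and directional libraries were read as paired ends of 42 bases. The genes knocked down were SART1, DDX39A, SARNP, FIBP and TMEM259 (also called C19orf6), each with 2 siRNAs in 2 libraries each. A non-targeting siRNA gave 2 control libraries for each of 3 tables, 1 for SART1, 1 for DDX39A and SARNP, and 1 for FIBP and TMEM259. Sample titles name these controls NTC in the DDX39A and SARNP table and NEGsiRNA in the other 2. Whether the same control siRNA served all tables is not stated. The 2 labels that misspell a target ("SARPN siRNA9" and "FIPBkd6") were read as SARNP and FIBP. Whether the 2 libraries of a group came from separate transfections is not stated, so they may be technical replicates.

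The submitters' processing notes name the human build hg19, STAR, Picard, HTSeq and DESeq2, without versions or roles, and do not state the annotation or the strand counted. The deposited values are normalized signal per gene symbol, made by the authors by dividing gene counts by 1 size factor per library. Within each library every value was a whole multiple of 1 step (tolerance 0.0001 of a read), from which whole reads and size factors were recovered. The deposited tables hold 11679 genes (DDX39A and SARNP), 12140 genes (FIBP and TMEM259) and 11823 genes (SART1). The rule that limited them to these genes is not stated, and the near-identical paralog of DDX39A, DDX39B, is not listed in the table used here. Reads without a gene, ambiguous reads and, in 2 tables, reads aligned more than once have entries of their own, which were kept apart from the genes.

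Gene reads per library ranged from 9959064 to 18086176 in the DDX39A and SARNP table, from 8966609 to 17018483 in the FIBP and TMEM259 table and from 21710821 to 26128173 in the SART1 table. The spread between the libraries of a group exceeded counting error, with a chi-square of 1.51 to 2.93 per degree of freedom.

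The genes, lists, tests and alternatives below were fixed before the data were examined, except where stated otherwise. Genes with a mean of at least 10 over their table were tested, 11673, 11768 and 11823 genes in the order above. Values were log2-transformed after adding 1, and 1 model per table with a mean for each group was fitted with limma 3.58.1 (lmFit, contrasts.fit and eBayes with trend) in R 4.3.3. The 3 tables were never merged, since they were normalized apart. A gene was called at a Benjamini-Hochberg adjusted p below 0.05, two-sided. A gene was called by both siRNAs of a target when each siRNA called it with the same sign. The contrasts were each siRNA against its controls, 1 siRNA against the other of the same target, the mean of both siRNAs against controls, SARNP against DDX39A, and TMEM259 against FIBP. Residual degrees of freedom were 5, 5 and 3, with prior degrees of freedom of 31.8, 38.4 and 20.5. Because both siRNAs of a target, and both targets of a shared table, have the same 2 controls, the correlation, covariance and overlap that shared controls give with no effect were simulated.

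Of 25 gene lists written from textbook knowledge, 23 were tested. The list of the 5 knocked-down genes was not tested, and mitochondrially encoded mRNAs had 0 measured members. A list needed at least 2 measured members, and the knocked-down gene was taken out of its own lists. The lists were tested with camera (preset correlation of 0.01, with the mean-variance trend) on the mean of both siRNAs, adjusted over all 115 tests of a list in a target. The same test with the correlation estimated from the data and fry, which asks whether a list's genes move on balance in 1 direction, were run as alternatives. All of these take their error from libraries within an siRNA and leave out the spread between the 2 siRNAs of a target. A called list therefore need not be an effect of the target. For each list, members called by both siRNAs are given from the adjustment over all genes and adjusted over the list alone.

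Named genes followed a rule: the knocked-down gene, up to 8 genes that rose and 8 that fell with the largest smaller change of the 2 siRNAs (both calls of 1 sign, every knockdown library beyond both control libraries, mean of at least 50, no clone-based names or pseudogenes), up to 4 members of each list called by both siRNAs with the largest mean change, and up to 4 genes in each direction for each contrast between targets. The text names a selection of these, and counts cover the rest. Some results the rule would name are not reported here, because the items are withheld.

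The alternatives were a pseudocount of 5, no filter and a mean of at least 50, quantile normalization, edgeR 4.0.16 with TMM and DESeq2 1.42.0 on the recovered reads, a fit of the compared libraries alone, a replicate number as a block, adjusting the larger of the 2 p-values, and leaving out each library in turn. For the correlations between siRNAs, these alternatives were added after the data were seen.

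The approach was tested on simulated data with known changes, made from the control means and the spread between libraries. Both siRNAs called between 47.9% and 58% of genes changed 1.25-fold, and all of those changed 4-fold, with at most 1 false call by both siRNAs per target. In every target 10 of 10 shifted lists and 0 of 40 unchanged lists were called, with the preset and with the estimated correlation. Because both correlations gave the same calls here, the simulation cannot decide between them for the real lists. There the preset correlation called 49 of 115 list tests and the estimated correlation called 0. First fits of the real values had been looked at before these simulations and before the tests of the closing section were written down, though the values those tests measure had not.

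Gene architecture had been planned only for an annotation of the build the files use. GENCODE release 29 is on another build, so it was matched by symbol, without coordinates, and 11841 of 12239 genes (96.7%) matched. Words of 7 bases were searched in 3' UTRs of at least 50 bases, known for 11219 genes. For each siRNA, every word was scored by the fold changes of genes holding it (a z value, negative when those genes were lower), against 20 shuffles of the genes. The 2 lowest-scoring words of an siRNA are called its low words here, and the word scoring highest over the siRNAs of 2 tables is called the control word. In a simulation 5 of 5 planted words ranked first. The shuffles do not keep the base composition of UTRs, which makes them lenient, and the labels give no siRNA sequences, so no word can be matched to a guide. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.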

Results

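RNA of 786-O cells, a clear cell renal carcinoma line, was sequenced after siRNA knockdown of genes whose proteins the series places in nuclear speckles, the nuclear bodies that hold splicing and mRNA export factors. The 26 libraries formed 13 groups of 2, namely 3 groups of control cells given a non-targeting siRNA and 10 groups given 1 siRNA each, with 2 siRNAs against each of SART1, DDX39A, SARNP, FIBP and TMEM259. Each table of values held its own pair of control libraries. The shallowest library was FIBP siRNA 7 replicate 1 with 8966609 gene reads, and the deepest was SART1 siRNA 6 replicate 1 with 26128173. Values below are normalized signal per gene, written as mean ± SD with n = 2 libraries, and fold changes are log2 values of an siRNA against the controls of its table with the SE of the model.

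Each siRNA lowered the mRNA it was aimed at, in each of its libraries. DDX39A, an RNA helicase of mRNA export, stood at 3209 ± 89.5 (SD, n = 2) in control cells, 449 ± 2.57 with siRNA 1 and 531 ± 14 with siRNA 4, which is 14% and 16.5% of control. SARNP, an RNA-binding partner of the export complex TREX, fell from 924 ± 24.7 (SD, n = 2) to 13.5% of control with siRNA 3 and 8.48% with siRNA 9. Its 3' UTR holds a low word of siRNA 9, in the sense defined in the processing, as is the control word named further on. FIBP, a protein that binds the growth factor FGF1, fell from 540 ± 0.986 (SD, n = 2) to 11% with siRNA 6 and 17.1% with siRNA 7. TMEM259, a membrane protein of the endoplasmic reticulum also called membralin, fell from 2209 ± 86.2 (SD, n = 2) to 30.3% with siRNA 5, of which its 3' UTR holds a low word, and to 48.3% with siRNA 6, the largest share left by any of the 10 siRNAs. SART1, which recruits the U4/U6.U5 tri-snRNP to the spliceosome, fell from 3324 ± 142 (SD, n = 2) to 33.3% with siRNA 4 and 26.8% with siRNA 6. The log2 changes of the 10 siRNAs ranged from -3.55 (SE 0.08, adjusted p = 1.4e-29) for SARNP siRNA 9 to -1.05 (SE 0.05, adjusted p = 1.3e-20) for TMEM259 siRNA 6. Some of the genes also moved in the knockdown of another. SARNP rose by 0.75 and 0.86 (SE 0.04) with the SART1 siRNAs, with an adjusted p of 1.1e-13 and 8.9e-15, and FIBP fell by 0.41 and by 0.47 (SE 0.07), with an adjusted p of 1.4e-05 and 2.1e-06.

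**Figure D1:**
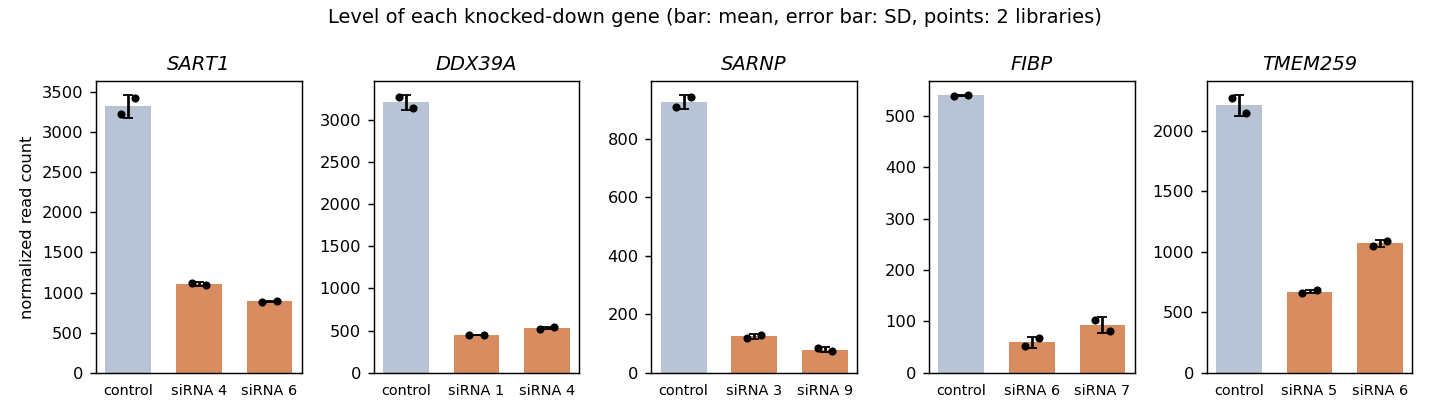
Signal of each knocked-down gene (y axis, normalized signal) in every library of its control group and of its 2 siRNAs (x axis), with points for libraries. Each siRNA lies below its controls, from 8.48% of control (SARNP siRNA 9) to 48.3% (TMEM259 siRNA 6).

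The number of genes called differed between targets and, for most, between the 2 siRNAs of a target, and between tables it also depends on depth and is no size of effect. SART1 siRNA 6 called 3841 genes up and 3601 down, and SART1 siRNA 4 called 3487 and 3337, while TMEM259 siRNA 6 called 1102 up and 1180 down, the fewest. Most changes were small, with a median absolute log2 change of called genes between 0.25 and 0.39, and between 24 genes (TMEM259 siRNA 6) and 665 genes (SARNP siRNA 9) changed over 2-fold. With both siRNAs 2709 genes rose and 2362 fell after SART1 knockdown, where independent lists would share 1133 and 1016. DDX39A gave 1012 up and 744 down (503.1 and 446.9 with independent lists), SARNP 837 and 835 (689.2 and 720.5), FIBP 551 and 517 (210.7 and 242.9) and TMEM259 301 and 284 (119.3 and 141.4). The count of 585 for TMEM259 fell to 279 without control replicate 1 and to 291 with DESeq2, where independent lists would share 85.5 and 82. With DESeq2 the counts also fell for FIBP (1068 to 596, 165 from independent lists), DDX39A (1756 to 1063, 448) and SARNP (1672 to 1080, 798), and for FIBP without control replicate 1 (677, 221) or 2 (711, 227). Both siRNAs of a target share their control libraries, which by itself gave a correlation of 0.50 to 0.51 in simulations without any effect, so the covariance beyond that is given too. Across genes, which are not independent replicates, the fold changes of the 2 SART1 siRNAs correlated at r = 0.75, with an excess covariance of 0.108. The values were r = 0.35 and 0.0347 for DDX39A, r = 0.31 and 0.0152 for FIBP, r = 0.33 and 0.00679 for TMEM259, and r = 0.04 and -0.00214 for SARNP. Simulations without an effect gave at most 1 gene called by both siRNAs. With no gene changed, the adjustment leaves few calls by either siRNA. That number therefore cannot bound the joint calls that shared controls add where many genes are called.

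**Figure D2:**
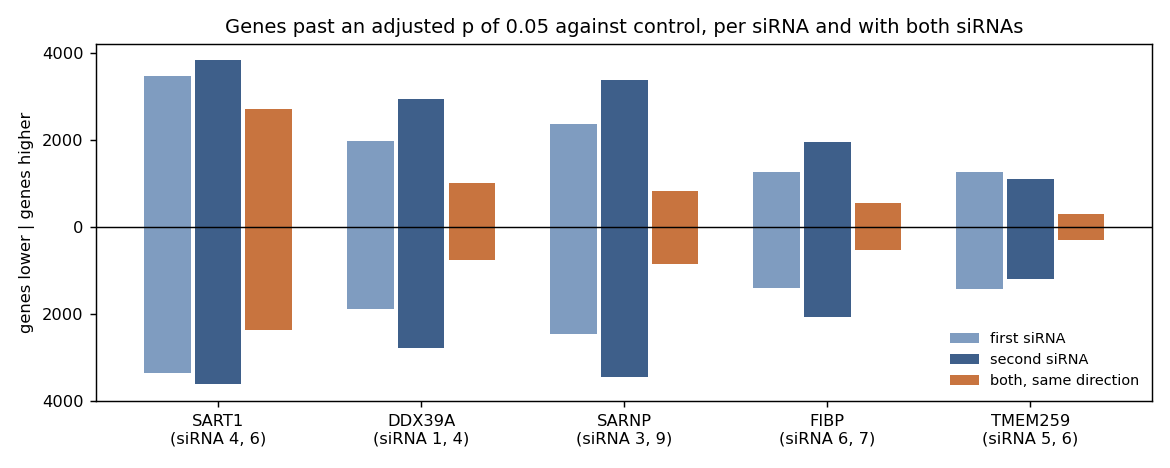
Genes called up and down (y axis, number of genes) by each siRNA and by both siRNAs of each target (x axis). SART1 had the most genes called by both (2709 up and 2362 down) and TMEM259 the fewest (301 up and 284 down).

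SART1 was knocked down to ask which genes depend on a factor that joins the tri-snRNP to the spliceosome. CXCL8, IL6 and CSF2 rose with both siRNAs, and LUCAT1 fell. CXCL8, a chemokine that draws neutrophils and whose 3' UTR holds a low word of siRNA 4, went from 486 ± 17 (SD, n = 2) to 1380 ± 180 with siRNA 4 and 1570 ± 53 with siRNA 6. Its log2 changes were 1.49 and 1.69 (SE 0.07, adjusted p = 1.0e-14 and 9.1e-16). IL6, an inflammatory cytokine, went from 182 ± 3.4 (SD, n = 2) to 588 ± 94 and 381 ± 16 (log2 1.68 and 1.06, SE 0.09). CSF2, which encodes the growth factor GM-CSF, went from 56.4 ± 0.25 (SD, n = 2) to 120 ± 9.7 and 173 ± 6.5 (adjusted p = 7.2e-07 and 1.0e-09). The long noncoding RNA LUCAT1 fell from 138 ± 0.3 (SD, n = 2) to 42.1 ± 12 and 34.1 ± 2.2 (log2 -1.72 and -1.99, SE 0.20). Others among the largest changes were SUCO, a membrane protein of the endoplasmic reticulum (1.09 and 1.00, SE 0.04), and NR1D1, a repressor of the circadian clock (1.00 and 1.05, SE 0.11). Downward they included SAMD11, a nuclear repressor (-1.24 and -1.33, SE 0.08), and DHRS11, an oxidoreductase (-1.11 and -1.42, SE 0.13). MEGF6, a secreted protein with EGF repeats, fell by 1.70 and by 1.14 (SE 0.07), and its 3' UTR holds a low word of siRNA 6. All 16 genes named by the rule on size passed with both siRNAs, at an adjusted p of at most 8.1e-05.

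Most measured genes of the speckle and tri-snRNP lists rose in the SART1 knockdown. Counts of members in this and the following SART1 lists stand against 2709 of all 11823 tested genes that rose with both siRNAs and 2362 that fell. Of 47 measured genes for speckle and SR proteins, 30 rose and 5 fell with both siRNAs, the same numbers when adjusted over the list alone (camera adjusted p = 3.0e-05; adjusted p = 0.161 with an estimated correlation). SRRM1, a splicing coactivator, rose by 0.70 and 0.92 (SE 0.05). NEAT1, the long noncoding RNA that builds paraspeckles, fell from 2770 ± 39 (SD, n = 2) to 1320 ± 12 and 968 ± 15 (log2 -1.07 and -1.52, SE 0.05). Of 29 genes of the tri-snRNP itself, 21 rose and 1 fell, 22 and 1 adjusted over the list alone (camera adjusted p = 4.6e-06; adjusted p = 0.161 with an estimated correlation). PRPF3, a U4/U6 protein, rose by 0.74 and 1.01 (SE 0.04), and SNRNP27, PRPF4 and PPIH, also tri-snRNP proteins, rose by 0.48 to 0.80 with each siRNA. Of 28 genes of TREX and mRNA export, 12 rose and 1 fell, 14 and 1 adjusted over the list alone (camera adjusted p = 0.00853; adjusted p = 0.351 with an estimated correlation). MAGOH, a core part of the exon junction complex, rose by 0.45 and 0.36 (SE 0.04) and PCID2, of the TREX-2 complex, fell by 0.28 and by 0.55 (SE 0.06). The export call was lost after quantile normalization (adjusted p = 0.276, with 0.00236 to 0.351 over its 16 alternatives).

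In the same cells 31 of 41 genes for DNA replication and entry into S phase fell and 1 rose, 33 and 1 adjusted over the list alone (camera adjusted p = 3.2e-11; adjusted p = 0.111 with an estimated correlation). E2F1, a transcription factor that drives S-phase genes, fell by 0.87 and by 0.95 (SE 0.05), its relative E2F2 fell by 0.90 and by 1.04 (SE 0.11). MCM7, a part of the replicative helicase, fell from 16700 ± 120 (SD, n = 2) to 10100 ± 360 and 10100 ± 200. The mitosis list had 15 of 41 genes up and 9 down, 15 and 10 adjusted over the list alone, and was called up by fry (adjusted p = 0.016) but not by camera (adjusted p = 0.262). NF-kB targets and inflammatory cytokines rose in 20 of 24 cases and fell in 0, the same numbers adjusted over the list alone (camera adjusted p = 2.9e-09; adjusted p = 0.362 with an estimated correlation). CCL20, a chemokine for lymphocytes, rose from 8.82 ± 0.07 (SD, n = 2) to 28.9 ± 0.33 and 23.7 ± 2.3. Among 23 genes of MAPK output 14 rose and 0 fell, also when adjusted over the list alone (camera adjusted p = 9.5e-06; adjusted p = 0.343 with an estimated correlation). They included DUSP5, a phosphatase that restrains ERK (1.78 and 0.75, SE 0.08), and SPRY2, an inhibitor of receptor signalling (0.93 and 0.64, SE 0.10). Interferon-response genes went the other way, with 14 of 28 down and 1 up, as when adjusted over the list alone (camera adjusted p = 7.7e-04; adjusted p = 0.194 with an estimated correlation). IFI44, an interferon-induced gene, fell by 1.11 and by 0.80 (SE 0.11), as did IFIT1, a sensor of viral RNA whose 3' UTR holds a low word of siRNA 6 (-1.24 and -0.58, SE 0.10).

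Many genes of protein folding and quality control rose after SART1 knockdown. Of 31 genes for chaperones and degradation at the endoplasmic reticulum 23 rose and 0 fell, as when adjusted over the list alone (camera adjusted p = 4.3e-08; adjusted p = 0.194 with an estimated correlation). SEC24D, a coat protein of export vesicles, went from 2660 ± 120 (SD, n = 2) to 5480 ± 350 and 5120 ± 2.8 (log2 1.05 and 0.95, SE 0.04). HERPUD1, a stress-induced degradation factor, rose by 1.00 and 0.70 (SE 0.05). In the heat shock list 8 of 16 rose, 9 adjusted over the list alone (camera adjusted p = 0.0117; adjusted p = 0.472 with an estimated correlation). DNAJB4, a cochaperone, rose by 0.69 and 0.40 (SE 0.05). In the proteasome list 13 of 31 rose and 1 fell, as when adjusted over the list alone (camera adjusted p = 0.0138; adjusted p = 0.404 with an estimated correlation). PSMD14, a deubiquitinase of the proteasome lid, rose by 0.31 and 0.40 (SE 0.03). For p53 targets 10 of 23 rose and 2 fell, 10 and 3 adjusted over the list alone (camera adjusted p = 0.00884; adjusted p = 0.367 with an estimated correlation). GDF15, a stress-induced cytokine, rose by 2.71 and 0.83 (SE 0.19). In cholesterol synthesis 9 of 23 rose, as when adjusted over the list alone (camera adjusted p = 0.0135; adjusted p = 0.554 with an estimated correlation). HMGCS1, an early enzyme of that pathway, rose by 0.38 and 0.92 (SE 0.05). Of 75 genes for cytosolic ribosomal proteins 10 rose and 1 fell, 6 and 1 adjusted over the list alone (camera adjusted p = 0.00872; adjusted p = 0.75 with an estimated correlation). The medians of that list were 0 and 0.15 for the 2 siRNAs.

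Quantile normalization turned the direction of the ribosomal list after SART1 knockdown (adjusted p = 0.0439) and of the proteasome list (adjusted p = 0.687). It ended the calls for heat shock (adjusted p = 0.533) and cholesterol synthesis (adjusted p = 0.0521). Over 16 alternatives each, the adjusted p ran from 0.00206 to 0.75, 0.0073 to 0.687, 0.00308 to 0.533 and 0.0036 to 0.554 in that order. The ribosomal call was also lost without control replicate 1 (adjusted p = 0.178) and with fry (adjusted p = 0.102).

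Hypoxia targets, the program that HIF-2 drives in this line, split after SART1 knockdown, with 8 of 37 up and 11 down, 8 and 12 adjusted over the list alone (camera adjusted p = 0.302). Of all 11823 tested genes 2709 rose and 2362 fell with both siRNAs, so a split is not by itself a feature of a list. NDRG1, a hypoxia-induced gene, fell by 0.72 and by 0.51 (SE 0.05), and BHLHE41, a transcriptional repressor whose 3' UTR holds a low word of siRNA 4, rose by 0.48 and 0.82 (SE 0.07). The glycolytic enzymes also split, with 4 of 16 up and 3 down, as when adjusted over the list alone (camera adjusted p = 0.302). ENO2, an enolase, fell by 0.76 and by 0.89 (SE 0.05), and HK2, a hexokinase, rose by 0.52 and 0.40 (SE 0.05). For ATF4 targets 8 of 27 rose and 2 fell, 8 and 3 adjusted over the list alone, and the list was called up by fry (adjusted p = 0.00653) but not by camera (adjusted p = 0.0738). GARS, a tRNA synthetase, rose by 0.73 and 0.47 (SE 0.04). Among 10 genes of kidney tubule identity 2 rose and 5 fell, as when adjusted over the list alone (camera adjusted p = 0.189; fry adjusted p = 0.026), with ANPEP, a brush-border peptidase, at -0.69 and -0.60 (SE 0.07).

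DDX39A was knocked down to ask which mRNAs change when an export helicase is low. With both siRNAs IL4I1, CCL2 and CDH6 rose, and MARCKSL1 fell. IL4I1, a secreted amino acid oxidase with no 3' UTR in the annotation used, went from 84.1 ± 14 (SD, n = 2) to 200 ± 12 with siRNA 1 and 368 ± 27 with siRNA 4 (adjusted p = 2.1e-09 and 6.1e-16). CCL2, a chemokine for monocytes, went from 59.1 ± 4 (SD, n = 2) to 126 ± 3.4 and 169 ± 17 (adjusted p = 4.7e-06 and 2.9e-09). PTX3, a secreted pattern-recognition protein, rose by 1.08 and 1.10 (SE 0.08), and TECPR2, an autophagy factor, by 1.31 and 1.24 (SE 0.12). Both of these genes hold the control word in their 3' UTR. TECPR2 was also called higher with both siRNAs of SARNP, FIBP and TMEM259. CDH6, a kidney cadherin, rose from 1060 ± 7.1 (SD, n = 2) to 2210 ± 260 and 2560 ± 180 although its 3' UTR holds low words of both siRNAs. Among genes that fell, MARCKSL1, an actin regulator, went from 670 ± 9.2 (SD, n = 2) to 228 ± 29 and 313 ± 11 (log2 -1.56 and -1.10, SE 0.08). The noncoding RNA DANCR fell by 1.14 and by 1.26 (SE 0.12). The 16 genes named by the rule on size passed with both siRNAs at an adjusted p of at most 1.9e-04.

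NF-kB targets and cytokines rose in 9 of 23 cases after DDX39A knockdown and fell in 1, as when adjusted over the list alone (camera adjusted p = 5.5e-07; adjusted p = 0.342 with an estimated correlation). ICAM1, an adhesion molecule for leukocytes, went from 1430 ± 23 (SD, n = 2) to 2640 ± 26 and 2150 ± 76 (log2 0.88 and 0.58, SE 0.05). RELB, an NF-kB subunit, rose by 0.81 and 0.55 (SE 0.09). Of 10 tubule identity genes 6 rose and 0 fell, as when adjusted over the list alone (camera adjusted p = 0.00468; adjusted p = 0.285 with an estimated correlation). GGT1, a peptidase of the brush border, rose by 0.35 and 0.71 (SE 0.05). PAX2, a regulator of kidney development, rose by 0.50 and 0.53 (SE 0.09). Of 28 matrix and mesenchymal genes 10 rose and 3 fell, as when adjusted over the list alone (camera adjusted p = 5.6e-06; adjusted p = 0.161 with an estimated correlation). FN1, which encodes fibronectin, went from 16800 ± 9.2 (SD, n = 2) to 20400 ± 850 and 47700 ± 2300, so that siRNA 4 carried most of its change (log2 0.28 and 1.51, SE 0.04). THBS1, a matrix glycoprotein, rose by 0.96 and 0.69 (SE 0.05). Hypoxia targets rose in 10 of 36 cases and fell in 4, 11 and 5 adjusted over the list alone (camera adjusted p = 7.4e-05; adjusted p = 0.257 with an estimated correlation). P4HA2, a collagen prolyl hydroxylase, rose by 0.61 and 0.68 (SE 0.05).

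Among genes for DNA replication 11 of 41 fell and 1 rose after DDX39A knockdown, as when adjusted over the list alone (camera adjusted p = 4.3e-08; adjusted p = 0.111 with an estimated correlation). In the mitosis list 6 of 41 fell and 0 rose, as when adjusted over the list alone (camera adjusted p = 5.1e-08; adjusted p = 0.194 with an estimated correlation). CCNE1, the cyclin of S-phase entry, fell by 0.90 and by 0.65 (SE 0.10), MCM10, a replication factor, fell by 0.30 and by 0.67 (SE 0.06). NUSAP1, a spindle protein, fell by 0.30 and by 0.24 (SE 0.04). The list medians with siRNA 1 and siRNA 4 were -0.05 and -0.33 (replication) and -0.01 and -0.27 (mitosis), a difference between siRNAs that was not tested. In the ribosomal list 5 of 75 genes fell, as when adjusted over the list alone (camera adjusted p = 1.4e-08; adjusted p = 0.617 with an estimated correlation; fry adjusted p = 0.136). In cholesterol synthesis 4 of 23 fell and 1 rose, 5 and 1 adjusted over the list alone (camera adjusted p = 0.0113; adjusted p = 0.367 with an estimated correlation). FDFT1, a squalene synthase, fell by 0.30 and by 0.24 (SE 0.07).

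With DDX39A low, ATF4 targets rose in 6 of 27 cases and fell in 1, 7 and 1 adjusted over the list alone (camera adjusted p = 0.00148; adjusted p = 0.161 with an estimated correlation). Chaperones of the endoplasmic reticulum rose in 6 of 31 cases and fell in 2, 6 and 3 adjusted over the list alone (camera adjusted p = 0.0152; adjusted p = 0.367 with an estimated correlation). SESN2, a stress-induced regulator of growth, rose by 0.33 and 0.84 (SE 0.08) and SEC24D by 0.26 and 0.68 (SE 0.05), but the ATF4 list had medians of -0.06 and 0.34. In the heat shock list, which was not called, 4 of 16 fell and 1 rose, as when adjusted over the list alone (camera adjusted p = 0.0806). MAPK output rose in 3 of 25 genes, as when adjusted over the list alone (camera adjusted p = 0.00576; adjusted p = 0.161 with an estimated correlation). EPHA2, a receptor kinase, rose by 0.24 and 0.43 (SE 0.04). Interferon-response genes rose in 5 of 29 cases, as when adjusted over the list alone (camera adjusted p = 0.0349; adjusted p = 0.472 with an estimated correlation). IRF1, a transcription factor of that response, rose by 0.79 and 0.36 (SE 0.06). The interferon call was lost without control replicate 1 (adjusted p = 0.0827) and without siRNA 1 replicate 1 (adjusted p = 0.0999). A mean of at least 50 (adjusted p = 0.0596) and DESeq2 (adjusted p = 0.0538) also ended it, with 0.00897 to 0.472 over its 16 alternatives.

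The lists closest to DDX39A itself were not called by camera, while fry placed all 3 lower (adjusted p = 0.0337 for export, 0.0364 for speckles and 0.026 for the tri-snRNP). Of 28 genes of TREX and mRNA export 4 fell and 0 rose, as when adjusted over the list alone (camera adjusted p = 0.364). NCBP2, the small subunit of the cap-binding complex, fell by 0.41 and by 0.24 (SE 0.05). In the speckle list 3 of 47 rose and 2 fell, as when adjusted over the list alone (camera adjusted p = 0.144). NEAT1 fell from 823 ± 28 (SD, n = 2) to 454 ± 3 and 462 ± 25 (log2 -0.86 and -0.83, SE 0.08). SRRM2, a scaffold of speckles, rose by 0.40 and 0.33 (SE 0.04). In the tri-snRNP list 1 of 29 fell, PRPF38A, a spliceosome protein (-0.27 and -0.32, SE 0.05), as when adjusted over the list alone (camera adjusted p = 0.0633).

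SARNP was knocked down to ask the same of an RNA-binding partner of TREX. Its 2 siRNAs called many of the same genes, with largely unrelated signs. There were 837 genes up and 835 down with both, where independent lists would give 689.2 and 720.5, and 1517 in opposite directions, where they would give 1409. Genes moved by both siRNAs included DCP2, the enzyme that removes mRNA caps, which went from 645 ± 19 (SD, n = 2) to 1490 ± 24 with siRNA 3 and 1610 ± 36 with siRNA 9. Its log2 changes were 1.21 and 1.32 (SE 0.06, adjusted p = 2.0e-19 and 4.6e-21). HGD, an enzyme of tyrosine breakdown, went from 144 ± 5.2 (SD, n = 2) to 308 ± 12 and 381 ± 14, and FAH, the last enzyme of that pathway, rose by 1.23 and 1.00 (SE 0.07). So did ITGB6, an integrin of epithelia (1.02 and 1.06, SE 0.16), and RIN1, a Ras effector (1.10 and 1.16, SE 0.10). CXCL8, whose 3' UTR holds a low word of siRNA 3, fell from 230 ± 34 (SD, n = 2) to 63.9 ± 12 and 82.1 ± 14 (log2 -1.84 and -1.48, SE 0.15). TGFB1I1, a focal adhesion protein, fell by 0.95 and by 0.94 (SE 0.11). The 16 genes named by the rule on size passed with both siRNAs at an adjusted p of at most 2.1e-05.

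Among NF-kB targets and cytokines 7 of 23 fell and 1 rose after SARNP knockdown, as when adjusted over the list alone (camera adjusted p = 0.00148; adjusted p = 0.45 with an estimated correlation). IL6 fell from 89.9 ± 1.2 (SD, n = 2) to 48.2 ± 6.2 and 51.8 ± 6 (log2 -0.89 and -0.79, SE 0.17). CXCL1, a neutrophil chemokine whose 3' UTR holds a low word of siRNA 9, fell from 51.6 ± 3.5 (SD, n = 2) to 12 ± 2.3 and 23.9 ± 1.5. In the ribosomal list 20 of 75 genes fell and 0 rose, 17 adjusted over the list alone (camera adjusted p = 1.7e-08; adjusted p = 0.617 with an estimated correlation; fry adjusted p = 0.105). RPS7, of the small subunit, fell by 0.28 and by 0.29 (SE 0.05). In the replication list 7 of 41 fell and 0 rose, as when adjusted over the list alone (camera adjusted p = 0.00226; adjusted p = 0.161 with an estimated correlation). RRM1, a subunit of ribonucleotide reductase, fell by 0.25 and by 0.34 (SE 0.05). Among p53 targets 5 of 23 rose and 0 fell, as when adjusted over the list alone (camera adjusted p = 0.0131; adjusted p = 0.194 with an estimated correlation). GDF15 went from 12.2 ± 0.81 (SD, n = 2) to 55 ± 0.47 and 66.7 ± 3.1 (log2 2.08 and 2.35, SE 0.24). CDKN1A, the inhibitor p21 of cyclin-dependent kinases, went from 598 ± 1.7 (SD, n = 2) to 1400 ± 63 and 915 ± 92 (log2 1.22 and 0.61, SE 0.07). The list medians were 0.21 and -0.01.

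The remaining called lists of SARNP rested on less. Among matrix genes 12 of 28 fell and 7 rose, as when adjusted over the list alone (camera adjusted p = 0.0275; adjusted p = 0.362 with an estimated correlation). COL1A1, a fibrillar collagen whose 3' UTR holds a low word of siRNA 3, fell by 0.92 and by 1.32 (SE 0.22) while the integrin ITGA5 rose by 0.26 and 0.72 (SE 0.04). Hypoxia targets rose in 12 of 36 cases and fell in 3, as when adjusted over the list alone, with medians of 0.30 and -0.09 (camera adjusted p = 0.0479; adjusted p = 0.472 with an estimated correlation). ANGPTL4, a hypoxia-induced inhibitor of lipoprotein lipase, went from 45.8 ± 15 (SD, n = 2) to 89.5 ± 15 with siRNA 3 and to 1840 ± 55 with siRNA 9. TGFA, a growth factor under HIF-2, rose by 0.98 and 0.70 (SE 0.04). In cholesterol synthesis 5 of 23 fell, as when adjusted over the list alone (camera adjusted p = 0.0214; adjusted p = 0.404 with an estimated correlation). LSS, the lanosterol synthase, fell by 0.54 and by 0.70 (SE 0.08), and the list medians were -0.31 and 0.02. In the mitosis list 1 of 41 fell and 2 rose, as when adjusted over the list alone (camera adjusted p = 0.0262; adjusted p = 0.529 with an estimated correlation). They were AURKA, a mitotic kinase whose 3' UTR holds a low word of siRNA 3 (-0.84 and -0.19, SE 0.04), AURKB, another mitotic kinase (0.22 and 0.22, SE 0.05), and CCNA2, a cyclin (0.17 and 0.21, SE 0.04). Camera called the mitosis list down, although more members rose than fell with both siRNAs. Its medians were 0.11 with siRNA 3 and -0.24 with siRNA 9.

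Several of these SARNP calls were lost when 1 library was left out. The hypoxia call was lost without control replicate 1 (adjusted p = 0.0605), siRNA 3 replicate 2 (adjusted p = 0.0599) or siRNA 9 replicate 1 (adjusted p = 0.0738). The mitosis call was lost without control replicate 2 (adjusted p = 0.106), siRNA 3 replicate 2 (adjusted p = 0.0623) or siRNA 9 replicate 1 (adjusted p = 0.0517). Matrix genes lost theirs without control replicate 1 (adjusted p = 0.0561) and cholesterol synthesis without control replicate 2 (adjusted p = 0.0559). Other settings did so for hypoxia (mean of at least 50, 0.0536), matrix (mean of at least 50, 0.0663; quantile normalization, 0.258), cholesterol (DESeq2, 0.0587) and mitosis (quantile normalization, 0.119). Over 16 alternatives the adjusted p ran from 0.00699 to 0.472, 8.1e-04 to 0.362, 0.00335 to 0.404 and 0.00575 to 0.529 in that order. The lists of speckle proteins (camera adjusted p = 0.222), the tri-snRNP (0.939) and mRNA export (0.878) were not called by camera, while fry called speckles down (adjusted p = 0.0117). THOC6, a TREX subunit, rose by 0.43 and 0.45 (SE 0.10).

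**Figure D3:**
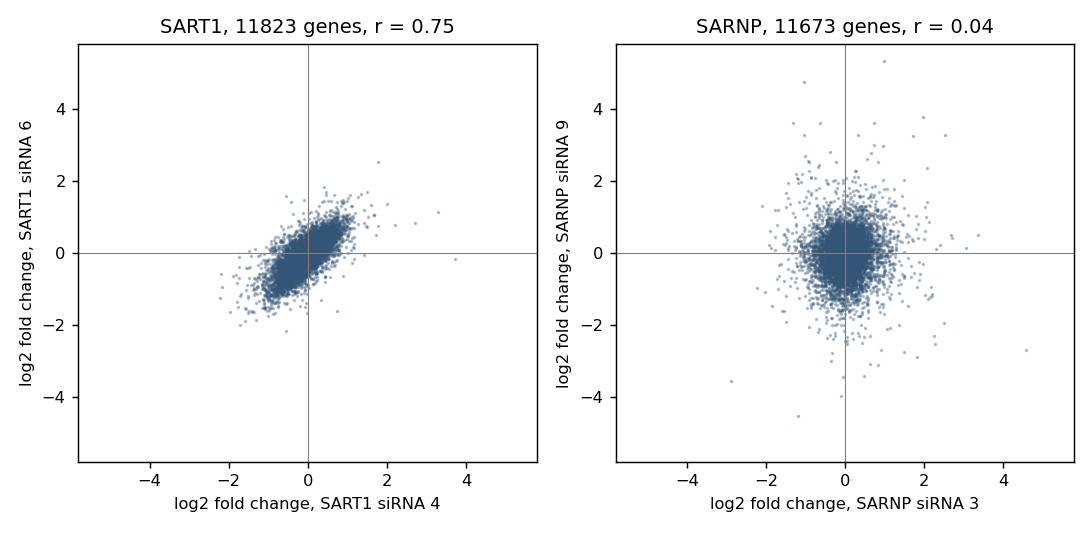
Log2 fold change of every tested gene with 1 siRNA (x axis) against the other (y axis), 1 point per gene, for SART1 and for SARNP. The SART1 siRNAs correlate across genes at r = 0.75 and the SARNP siRNAs at r = 0.04.

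SARNP and DDX39A, both partners of mRNA export, were compared directly within their table, where they share controls. The contrast called 3047 genes higher after SARNP knockdown and 3214 lower. Between the 2 siRNAs of the same target 7487 genes differed for SARNP and 5903 for DDX39A. The error of the contrast comes from libraries within an siRNA and leaves out the spread between siRNAs, so its calls need not be effects of the target. Inflammatory genes stood apart, with a median difference (SARNP minus DDX39A) of -0.62 in the NF-kB list (camera adjusted p = 4.3e-10; adjusted p = 0.219 with an estimated correlation). CLEC4E, a receptor of innate immunity, went from 85.2 ± 7.9 (SD, n = 2) in control cells to 56 ± 4 and 30.8 ± 4.2 after SARNP knockdown. It rose by 0.84 and 1.66 (SE 0.157) with the DDX39A siRNAs, a difference of -2.27 (SE 0.11, adjusted p = 1.4e-19). Matrix and mesenchymal genes differed by a median of -0.38 (camera adjusted p = 6.4e-09; adjusted p = 0.092 with an estimated correlation). Tubule identity genes differed by -0.27 (camera adjusted p = 0.0109; adjusted p = 0.285 with an estimated correlation) and mitosis genes by 0.04 (camera adjusted p = 0.0386; adjusted p = 0.647 with an estimated correlation). Several of the largest differences came from a single siRNA, such as SLC7A2, an amino acid transporter, at 459 ± 67 (SD, n = 2) with SARNP siRNA 3 and 60.3 ± 6 with siRNA 9 against 54.8 ± 10 in control cells. MEGF6 stood at 481 ± 35 (SD, n = 2) and 45.2 ± 7.8 against 499 ± 40. Called by both siRNAs of both targets were 276 genes up and 165 down, against 72.6 and 53.2 from independent lists, and 36 in opposite directions. Unchanged groups simulated against the shared controls gave at most 0 such genes, and part of the excess may still come from those controls.

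FIBP was knocked down to ask what changes when a speckle protein of the series outside the core splicing and export machinery is low. With both siRNAs DUSP5, a feedback inhibitor of MAPK signalling, and IL6 rose, and IGFBP1 fell. DUSP5 went from 89.3 ± 3.4 (SD, n = 2) to 177 ± 6 with siRNA 6 and 310 ± 1.3 with siRNA 7 (adjusted p = 1.5e-07 and 6.7e-15). IL6 went from 113 ± 27 (SD, n = 2) to 197 ± 8 and 227 ± 26 (log2 0.81 and 1.01, SE 0.14). DESI2, of a family of desumoylating peptidases, whose 3' UTR holds a low word of siRNA 7, went from 1080 ± 86 (SD, n = 2) to 2000 ± 12 and 1960 ± 56. INPP5A, an inositol phosphatase, rose by 0.84 and 0.64 (SE 0.08). DESI2 and INPP5A were also called higher with both siRNAs of DDX39A, SARNP and TMEM259, so their rise is not particular to FIBP. The largest rise of DESI2 was 1.19 with DDX39A siRNA 4, and that of INPP5A was 1.63 with SARNP siRNA 9. IGFBP1, a binding protein of insulin-like growth factors, fell from 101 ± 8.8 (SD, n = 2) to 55 ± 10 and 34.1 ± 9.2 (log2 -0.87 and -1.56, SE 0.20). ARTN, a neurotrophic factor, fell by 0.70 and by 0.94 (SE 0.10). TSPAN2, a tetraspanin whose 3' UTR holds a low word of siRNA 6, fell from 652 ± 64 (SD, n = 2) to 227 ± 12 and 346 ± 18.

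In the mitosis list 9 of 41 genes fell and 0 rose after FIBP knockdown, 9 and 1 adjusted over the list alone (camera adjusted p = 6.7e-11; adjusted p = 0.111 with an estimated correlation). In the replication list 16 of 41 fell and 0 rose, 18 and 0 adjusted over the list alone (camera adjusted p = 1.9e-09; adjusted p = 0.111 with an estimated correlation). CKAP2, a spindle protein, fell by 0.19 and by 0.39 (SE 0.04), CDK1, the kinase of mitotic entry whose 3' UTR holds a low word of siRNA 7, fell by 0.20 and by 0.50 (SE 0.04). E2F1, whose 3' UTR holds a low word of siRNA 6, fell by 0.39 and by 0.33 (SE 0.06). In the ribosomal list 13 of 75 fell and 0 rose, as when adjusted over the list alone (camera adjusted p = 3.6e-06; adjusted p = 0.472 with an estimated correlation). RPL41, of the large subunit, fell by 0.27 and by 0.17 (SE 0.04). NF-kB targets rose in 5 of 23 cases and fell in 0, as when adjusted over the list alone, with list medians of 0.43 and 0.04 (camera adjusted p = 1.4e-05; adjusted p = 0.437 with an estimated correlation). MAPK output rose in 5 of 20 genes and fell in 0, as when adjusted over the list alone (camera adjusted p = 1.8e-04; adjusted p = 0.161 with an estimated correlation). The medians of the MAPK list were 0.03 with siRNA 6 and 0.38 with siRNA 7. SPRED2, another inhibitor of that pathway, rose by 0.46 and 0.56 (SE 0.09). Of 23 p53 targets 5 rose and 0 fell, as when adjusted over the list alone (camera adjusted p = 4.6e-04; adjusted p = 0.161 with an estimated correlation). The medians of the p53 list were 0.08 with siRNA 6 and 0.32 with siRNA 7, and neither difference between siRNAs was tested. FAS, a death receptor, rose by 0.30 and 0.32 (SE 0.07). GDF15 went from 14.3 ± 3.8 (SD, n = 2) to 30.6 ± 1.5 and 41.3 ± 1.9, a call lost without control replicate 1 (adjusted p = 0.112).

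After FIBP knockdown hypoxia targets fell in 8 of 37 cases and rose in 1, 9 and 2 adjusted over the list alone, with list medians of -0.23 and 0.01 (camera adjusted p = 0.00189; adjusted p = 0.28 with an estimated correlation). ARRDC3, an arrestin-like regulator of membrane receptors, fell by 0.48 and by 0.46 (SE 0.06). IGFBP3, another binding protein of insulin-like growth factors, whose 3' UTR holds a low word of siRNA 6, fell from 11300 ± 610 (SD, n = 2) to 5130 ± 440 and 7550 ± 910. In cholesterol synthesis 5 of 24 fell and 0 rose, 7 and 0 adjusted over the list alone (camera adjusted p = 0.0108; adjusted p = 0.404 with an estimated correlation). That call was lost without control replicate 2 (adjusted p = 0.11, with 0.00132 to 0.404 over its 16 alternatives). The speckle list (camera adjusted p = 0.935), the tri-snRNP list (0.222) and the export list (0.689) were not called by camera, while fry called the tri-snRNP up (adjusted p = 0.00164). PRPF8, the central protein of the spliceosome, rose by 0.19 and 0.17 (SE 0.04). NDUFS3, a subunit of respiratory complex I, fell by 0.40 and by 1.55 (SE 0.08) in a respiratory list that was not called (camera adjusted p = 0.984).

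TMEM259 was knocked down to ask the same of a membrane protein of the series. By both siRNAs 1 gene, TMEM259 itself, changed over 2-fold. MMP13, a collagenase whose 3' UTR holds the control word, fell from 102 ± 20 (SD, n = 2) to 37 ± 0.66 with siRNA 5 and 52.7 ± 3.2 with siRNA 6 (adjusted p = 3.8e-08 and 1.3e-04). MMP2, a gelatinase, fell from 591 ± 18 (SD, n = 2) to 331 ± 34 and 390 ± 16 (log2 -0.84 and -0.60, SE 0.08). COL6A3, a chain of collagen VI, fell by 0.78 and by 0.46 (SE 0.06). PORCN, the enzyme that acylates Wnt proteins, fell from 405 ± 5.1 (SD, n = 2) to 229 ± 17 and 250 ± 2.6 (log2 -0.82 and -0.69, SE 0.10). MARCKSL1 fell by 0.86 and by 0.89 (SE 0.08), with a low word of siRNA 5 in its 3' UTR. CXCL5, a neutrophil chemokine whose 3' UTR holds a low word of siRNA 6, rose from 1930 ± 86 (SD, n = 2) to 3100 ± 280 and 2880 ± 120. TECPR2, which holds the control word, rose from 75.5 ± 15 (SD, n = 2) to 140 ± 7.2 and 133 ± 1.9. It was also called higher with both siRNAs of DDX39A, SARNP and FIBP. FILIP1L, an inhibitor of cell migration, rose by 1.29 and 0.90 (SE 0.20), a call lost without control replicate 2 (adjusted p = 0.0735).

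Hypoxia targets fell in 6 of 37 cases and rose in 2 after TMEM259 knockdown, 7 and 2 adjusted over the list alone (camera adjusted p = 0.00739; adjusted p = 0.343 with an estimated correlation). NDRG1 went from 3690 ± 200 (SD, n = 2) to 2440 ± 73 and 2680 ± 72 (log2 -0.59 and -0.46, SE 0.05). DDIT4, an inhibitor of mTORC1, fell by 0.49 and by 0.30 (SE 0.05). In the replication list 7 of 41 fell and 0 rose, 8 and 0 adjusted over the list alone (camera adjusted p = 3.0e-07; adjusted p = 0.111 with an estimated correlation). FEN1, a flap endonuclease of lagging-strand synthesis, fell by 0.25 and by 0.19 (SE 0.05). Its call was lost without control replicate 1 (adjusted p = 0.0925) or siRNA 6 replicate 1 (adjusted p = 0.064). In the respiratory list 7 of 73 fell and 0 rose, as when adjusted over the list alone, with list medians of -0.12 and 0 (camera adjusted p = 1.3e-04; adjusted p = 0.367 with an estimated correlation). In the tri-snRNP list 2 of 29 fell and 0 rose, 4 and 0 adjusted over the list alone (camera adjusted p = 0.0167; adjusted p = 0.194 with an estimated correlation). PRPF38A, whose 3' UTR holds low words of both siRNAs, fell by 0.28 and by 0.22 (SE 0.05). That call was lost without control replicate 2 (adjusted p = 0.0564) or siRNA 6 replicate 1 (adjusted p = 0.0674). The ribosomal list had 1 of 75 down and 0 up, as when adjusted over the list alone (camera adjusted p = 3.2e-12; adjusted p = 0.351 with an estimated correlation). The gene was RPL41 at -0.50 and -0.18 (SE 0.04), and the list medians were -0.20 and 0.05.

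The last called lists of TMEM259 rose or fell with siRNA 5 and had a median of the other sign with siRNA 6. NF-kB targets rose in 2 of 23 genes and fell in 1, as when adjusted over the list alone, with medians of 0.26 and -0.03 (camera adjusted p = 7.7e-04; adjusted p = 0.534 with an estimated correlation). In the proteasome list 1 of 31 fell, as when adjusted over the list alone, with medians of -0.11 and 0.03 (camera adjusted p = 0.00919; adjusted p = 0.194 with an estimated correlation). It was PSMD13, a subunit of the proteasome lid (-0.17 and -0.20, SE 0.04). Interferon-response genes rose in 1 of 28 cases, as when adjusted over the list alone, with medians of 0.32 and -0.04 (camera adjusted p = 0.0437; adjusted p = 0.362 with an estimated correlation). Without control replicate 1 the calls for NF-kB targets (adjusted p = 0.0796) and the proteasome (adjusted p = 0.0703) were lost. The interferon call was lost without control replicate 2 (adjusted p = 0.184), siRNA 5 replicate 1 (adjusted p = 0.078) and siRNA 6 replicate 2 (adjusted p = 0.112). It was also lost with a mean of at least 50 (adjusted p = 0.133), DESeq2 (adjusted p = 0.0999) and fry (adjusted p = 0.0505), and the NF-kB call with fry (adjusted p = 0.137). Over 16 alternatives the adjusted p ran from 2.4e-06 to 0.534 (NF-kB), 0.00237 to 0.194 (proteasome) and 0.0143 to 0.362 (interferon). The speckle list (camera adjusted p = 0.302) and the export list (0.657) were not called by camera, while fry called speckles down (adjusted p = 0.0398).

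TMEM259 and FIBP shared a table and controls and were compared directly. The contrast called 2214 genes higher after TMEM259 knockdown and 2152 lower. Between the 2 siRNAs of the same target 3776 genes differed for TMEM259 and 4197 for FIBP, a spread that the error of the contrast leaves out here too. DUSP5 stood at 104 ± 0.041 (SD, n = 2) and 97.1 ± 19 with the TMEM259 siRNAs against 89.3 ± 3.4 in control cells. With the FIBP siRNAs it stood at 177 ± 6 and 310 ± 1.3 (SD, n = 2), a difference of -1.22 (SE 0.09, adjusted p = 1.9e-14). MEGF6 stood at 668 ± 27 (SD, n = 2) and 675 ± 38 against 761 ± 23 in control cells. Its log2 changes with the FIBP siRNAs were -0.41 and -3.24 (SE 0.083), a difference of 1.65 (SE 0.06, adjusted p = 3.4e-26). SCG5, a chaperone of neuroendocrine secretion, differed by -1.32 (SE 0.07), with 186 ± 1.6 (SD, n = 2) and 162 ± 2 after TMEM259 knockdown against 273 ± 13 in control cells. Mitosis genes were higher after TMEM259 than after FIBP knockdown by a median of 0.12 (camera adjusted p = 6.4e-09; adjusted p = 0.092 with an estimated correlation). The other called differences were cholesterol synthesis (0.19, camera adjusted p = 2.2e-04; adjusted p = 0.285 with an estimated correlation), proteasome (-0.08, 2.2e-04; 0.092), tri-snRNP (-0.08, 0.00125; 0.092), p53 targets (-0.26, 0.00137; 0.177), respiratory genes (-0.07, 0.00257; 0.526), MAPK output (-0.21, 0.00292; 0.219), interferon response (0.12, 0.0199; 0.285) and tubule identity (0.08, 0.0386; 0.341), each with its median difference and the same pair of adjusted p. Called by both siRNAs of both targets were 117 genes up and 65 down, against 14.1 and 12.5 from independent lists, and 6 in opposite directions. The simulation gave at most 0 here as well, with the same limit from shared controls.

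Across the 5 targets, camera called 49 of 115 list tests, 26 up and 23 down. Genes for DNA replication were called down in all 5 knockdowns, and in 0 with an estimated correlation (adjusted p of at least 0.111). Their medians with the 2 siRNAs were -0.31 and -0.29 for SART1 and -0.15 and -0.21 for FIBP. They were -0.05 and -0.33 for DDX39A, -0.01 and -0.26 for SARNP, and -0.15 and -0.05 for TMEM259. In these last targets 1 siRNA carried most of the shift, a difference that was not tested. NF-kB targets were called up in 4 knockdowns and down after SARNP knockdown, and ribosomal proteins were called down in 4 and up after SART1 knockdown, in none with an estimated correlation (0.342 and 0.351 at the lowest). By camera, the list of nuclear speckle and SR proteins was called in the SART1 knockdown alone, as was the list of TREX and mRNA export. Targets were compared with each other only within the 2 shared tables, so this difference was not itself tested. Glycolysis (16 measured genes) was never called, with a camera adjusted p between 0.288 and 0.878. Neither were replication-dependent histones (2 to 4 measured, 0.325 to 0.939), single-exon genes (24 to 26 measured, 0.145 to 0.939) and markers of blood, endothelium and neurons (3 measured, 0.403 to 0.935). In the knockdowns where a list was not called, the adjusted p ran from 0.0633 to 0.939 for the tri-snRNP, 0.189 to 0.984 for respiratory genes, 0.0653 to 0.569 for heat shock and 0.0916 to 0.878 for the proteasome. It ran from 0.161 to 0.926 for p53 targets, 0.375 to 0.504 for interferon response, 0.0738 to 0.749 for ATF4 targets, 0.069 to 0.386 for chaperones of the endoplasmic reticulum and 0.104 to 0.51 for MAPK output. The values were 0.22 to 0.974 for matrix genes, 0.189 to 0.693 for tubule identity, 0.262 and 0.302 for mitosis, 0.302 for hypoxia and 0.233 for cholesterol synthesis. With the estimated correlation camera called 0 lists at a lowest adjusted p of 0.111, against 20 at an unadjusted p below 0.05, and fry called 68. In 47 of the 49 called lists that setting gave the highest adjusted p of all 16 alternatives, and in the other 2 quantile normalization did. The medians of the 2 siRNAs were not of 1 sign in 12 of the 49, and in 0 of the 49 did the list's median go against camera's direction.

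**Figure D4:**
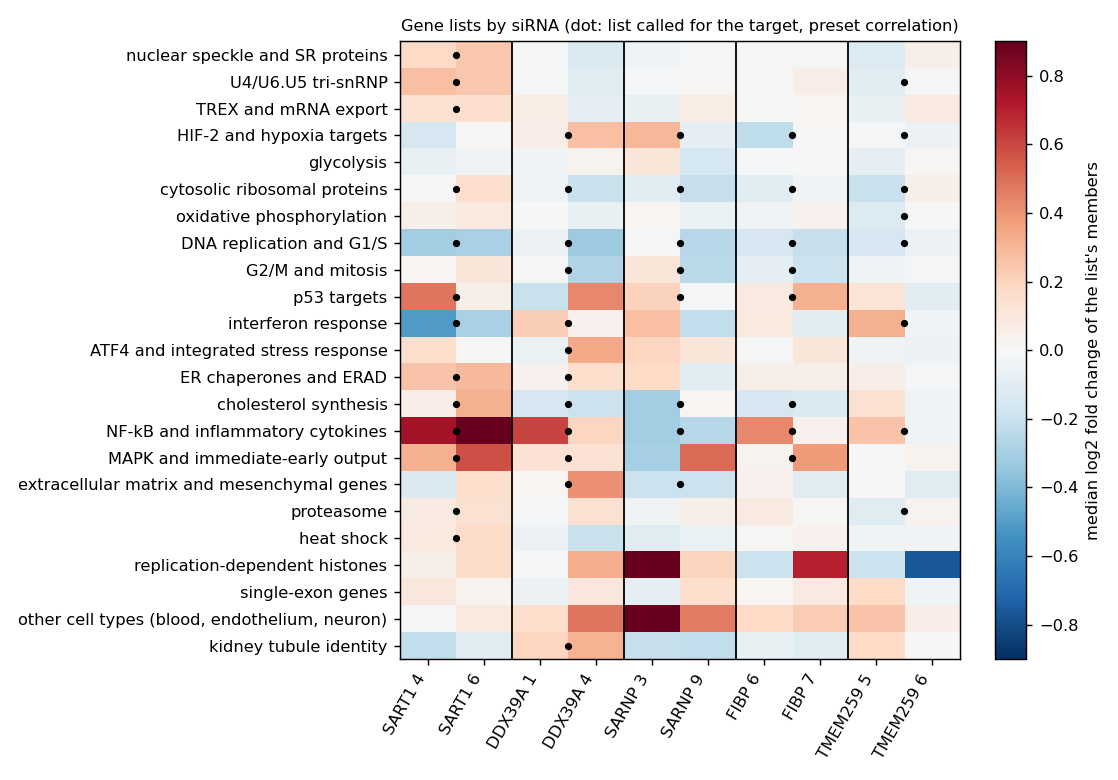
Median log2 fold change (color) of the measured genes of each list (y axis) with each siRNA (x axis), with a dot where the list was called for the target. DNA replication was called down in all 5 targets, and NF-kB targets were called up in 4 and down after SARNP knockdown, none of them with an estimated correlation (adjusted p of at least 0.111). The replication medians of the 2 siRNAs lay close for SART1 (-0.31 and -0.29) and apart for SARNP (-0.01 and -0.26).

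Targets in different tables share no control library, but an effect of the control siRNA common to the tables would also raise their overlaps. The control word ranked 1 in 2 of the tables (mean z 5.63 and 6.36). FIBP siRNA 7 and SART1 siRNA 4 also share a low word, CTAACAA (z = -12.66 and -10.88). FIBP and SART1 shared 317 genes up and 218 down, against 127 and 104 from independent lists, with 71 in opposite directions, and their mean fold changes correlated across genes at r = 0.35. The pair that shares the low word, FIBP siRNA 7 and SART1 siRNA 4, correlated at r = 0.49. FIBP siRNA 7 with SART1 siRNA 6 gave r = 0.21, and FIBP siRNA 6 gave r = 0.19 with SART1 siRNA 4 and 0.13 with SART1 siRNA 6. DDX39A and TMEM259 shared 130 up and 88 down (26.3 and 18.3 from independent lists; 7 opposite; r = 0.37), and FIBP and SARNP shared 140 and 93 (39.5 and 37.3; 37 opposite; r = 0.26). SARNP and TMEM259 shared 95 and 56 (21.6 and 20.5; 22 opposite; r = 0.26), and DDX39A and FIBP 133 and 81 (48 and 33.2; 72 opposite; r = 0.15). SART1 shared 317 and 221 with DDX39A (235 and 151; 338 opposite; r = 0.14), 284 and 232 with SARNP (194 and 170; 302 opposite; r = 0.10) and 155 and 89 with TMEM259 (69.6 and 57.3; 87 opposite; r = 0.14). Within a table the mean fold changes of DDX39A and SARNP correlated at r = 0.42, as did those of FIBP and TMEM259, below the r = 0.67 of unchanged groups simulated against the same controls. The covariances were 0.0411 for DDX39A and SARNP (0.0102 simulated) and 0.02 for FIBP and TMEM259 (0.012 simulated).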

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

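Of the tests in this part, the correlation over genes without the low words was chosen after the result was seen.

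SARNP and DDX39A moved some genes in opposite directions, which singled out 36 genes called by both siRNAs of both targets. These were few beside the 276 called up and 165 called down by both targets. The number of opposite genes from independent lists was not computed, so 36 is not shown to be an excess. Tests of the difference between the knockdowns set named genes apart, given here as SARNP minus DDX39A on the log2 scale. CLEC4E, a receptor of innate immunity, differed by -2.27, and CXCL1, a neutrophil chemokine whose 3' UTR holds a low word of SARNP siRNA 9, by -2.16. TNFAIP3, a feedback inhibitor of NF-kB that holds the control word, differed by -1.09. CYR61, a secreted matrix protein, differed by -0.88, and its rise after DDX39A knockdown was lost without control replicate 2 (adjusted p = 0.0888) and without siRNA 4 replicate 1 (adjusted p = 0.0594). The same contrast singled out NF-kB targets and cytokines (camera adjusted p = 4.3e-10; adjusted p = 0.219 with an estimated correlation) and matrix genes (camera adjusted p = 6.4e-09; adjusted p = 0.092 with an estimated correlation). When the 8 libraries of the 2 knockdowns were split into 4 and 4 in all 35 ways, the real split called 266 genes and ranked 3, behind splits calling 846 and 828. Both of those put 1 siRNA of each target together, which points to a structure of the samples by siRNA. All splits that part the 2 libraries of an siRNA called 0 genes, and the 3 that keep them together are too few for a share under 0.05.

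TMEM259 and FIBP moved 6 genes in opposite directions by both siRNAs, few beside the 117 called up and 65 called down by both targets. Here too 6 is not shown to be an excess. Among the 6 genes TRIAP1, an inhibitor of apoptosis, differed by -0.54 (TMEM259 minus FIBP). Its rise after FIBP knockdown was lost without control replicate 2 (adjusted p = 0.0629) and siRNA 6 replicate 1 (adjusted p = 0.0584), and its fall after TMEM259 knockdown in 9 settings, at an adjusted p of up to 0.63. Of the 35 splits of these 8 libraries the real one ranked 1 with 294 genes, against 196 in the highest other. Here too only the 3 splits that keep the 2 libraries of each siRNA together called any gene (294, 196 and 78), and 3 are too few for a share under 0.05.

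The 2 siRNAs of each target differed as well, which singled out the genes they called in opposite directions. There were 602 for DDX39A, 294 for FIBP, 1517 for SARNP, 286 for SART1 and 255 for TMEM259, against 948.3, 452.6, 1409, 2146 and 259.8 from independent lists.

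For SARNP, the target with more such genes than independent lists give, a candidate explanation is that each siRNA lowers its own set of other mRNAs through short matches in their 3' UTRs. In the fold changes of siRNA 3 the lowest word was GCTCCAC (z = -10.24 over 1050 genes; lowest in shuffles -4.86), and in those of siRNA 9 it was GCCTAAA (z = -19.22 over 1031 genes; lowest in shuffles -5.07), and each was near 0 with the other siRNA (z = -0.49 and 0.3), which fits that explanation. Genes holding GCCTAAA had a median of -0.20 with siRNA 9, against 0.02 without it. Genes without any of the low words still correlated at r = 0.04 across genes, which argues against the genes holding them being the whole cause. It cannot decide on short matches in general, since genes with other low-scoring words stayed in. With siRNA 9 these words included AGCCTAA (z = -13.05) and GCCTAAT (z = -9.49). Changes that follow from the lowered mRNAs would stay in as well. Noise between libraries is argued against, as fold changes from replicates sharing no library correlated at 0.74 and 0.87 for the 2 siRNAs. The difference in remaining SARNP (13.5% and 8.48% of control) was not tested as a biological explanation, and the cause stays open.

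Reads outside genes were singled out where both libraries of a knockdown lay above both of its controls. The lower library of SARNP siRNA 3 had 6.275% of reads without a gene, against at most 6.095% in controls, and that of FIBP siRNA 7 had 5.977% against 5.913%. In the opposite direction, SARNP siRNA 9 (5.955% and 5.959%) and DDX39A siRNA 4 (5.791% and 5.842%) lay below both controls (6.002% and 6.095%). Reads in more than 1 gene made up at least 1.407% with TMEM259 siRNA 6 against 1.388%, and at least 1.417% with SART1 siRNA 4 and 1.401% with SART1 siRNA 6 against 1.39%. All 4 siRNAs of the DDX39A and SARNP table lay below both controls there (at most 1.631% against 1.641%), as did TMEM259 siRNA 5 (1.331% and 1.342% against 1.378%) and FIBP siRNA 6 (1.36% and 1.376%). Reads aligned more than once made up at least 21.479% with FIBP siRNA 7 against 21.377%. TMEM259 siRNA 5 (20.69% and 20.561%), TMEM259 siRNA 6 (21.274% and 21.216%) and FIBP siRNA 6 (21.291% and 21.202%) lay below both controls (21.318% at the lower), so these shares followed no common direction.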

How the results depend on the processing

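For the correlations between siRNAs, the tests under other settings were chosen after the result was seen. Of 423 named-gene results 276 kept their call in every setting, and of 49 called lists 33 did, the estimated correlation aside. Counts within 1.5 times of the main count are not repeated here. With DESeq2 on the recovered reads the genes changed by DDX39A_si1 (siRNA 1) were 2439, the genes changed by FIBP_si6 1541, the genes changed by FIBP_si7 2519, the genes changed by TMEM259_si5 1552 and the genes changed by TMEM259_si6 1246. The genes changed by both DDX39A siRNAs were then 1063, the genes changed by both FIBP siRNAs 596, the genes changed by both SARNP siRNAs 1080 and the genes changed by both TMEM259 siRNAs 291. The genes differing between the FIBP siRNAs were 2621, the genes differing between the SART1 siRNAs 2961 and the genes differing between the TMEM259 siRNAs 2427. Adjusting the larger of the 2 p-values left 310 genes for TMEM259. Camera with an estimated correlation called 0 lists for DDX39A, 0 for FIBP, 0 for SARNP, 0 for SART1 and 0 for TMEM259, against 6, 4, 2, 5 and 3 at an unadjusted p below 0.05, while fry called 13 for FIBP and 13 for SARNP. Quantile normalization reversed 2 SART1 lists, ribosomal proteins (adjusted p = 0.0439) and proteasome (adjusted p = 0.687). Correlations of the 2 siRNAs across genes, with shared controls, moved for FIBP to 0.33 with no filter, 0.29 with a mean of at least 50 and 0.32 with quantile normalization, for SART1 to 0.73 with quantile normalization and for TMEM259 to 0.27 with a mean of at least 50. The cause was not tested in any of these. Leaving out 1 library, where a lone library is assumed to vary like the other groups, gave 1669 to 2168 genes for FIBP siRNA 6 (2660 in full), 677 to 953 for both FIBP siRNAs (1068), 1514 to 1876 for TMEM259 siRNA 5 (2684), 1080 to 1716 for TMEM259 siRNA 6 (2282), 279 to 452 for both TMEM259 siRNAs (585) and 2429 to 2984 between the TMEM259 siRNAs (3776), as fewer samples were fitted. The correlations then ran from 0.31 to 0.41 (DDX39A), 0.28 to 0.38 (FIBP), 0.01 to 0.1 (SARNP), 0.72 to 0.76 (SART1) and 0.27 to 0.46 (TMEM259). Named genes were lost most often with DESeq2 (69 of 407) and on leaving out a library (344 of 2570). Besides the 49 of 49 with an estimated correlation, lists were lost with quantile normalization (5 of 49, and 2 reversed), fry (5 of 49), a mean of at least 50 (4 of 49), DESeq2 (3 of 49) and on leaving out a library (17 of 294). With the replicate number as a block no count moved by more than 1.5 times (37 of 37 the same), and 6 of 423 named-gene results and 0 of 49 lists were lost. Differences between replicate 1 and replicate 2 correlated across genes from group to group at -0.06 to 0.05, which gives no sign that the numbers pair libraries. Depth of 8966609 reads in FIBP siRNA 7 replicate 1, against 21710821 or more in the SART1 table, limits the calling of small changes in weakly expressed genes there, and counts of calls should not be compared between tables as sizes of effect.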

Other observations

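Of the tests in this part, the share of genes with the control word at matched 3' UTR length was chosen after the result was seen, as were the genes named.

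A set of 32 genes was called higher with all 8 siRNAs of DDX39A, SARNP, FIBP and TMEM259. Those named here belong to the secretory and endolysosomal system, were picked after their values were seen, and no list of that system was tested. SRPRA and SRPRB, the 2 subunits of the receptor that brings ribosomes to the endoplasmic reticulum, rose by 0.25 to 0.89 and by 0.26 to 0.85 over the 8 siRNAs. SEC24A, a coat protein of vesicles that leave the endoplasmic reticulum and a holder of the control word, rose by 0.48 to 1.04. M6PR and IGF2R, the receptors that sort enzymes to lysosomes, rose by 0.14 to 0.57 and by 0.11 to 0.60. CSGALNACT2, an enzyme of chondroitin sulfate synthesis in the Golgi that holds the control word, rose by 0.51 to 1.22, and OCRL, a phosphatase of membrane traffic, by 0.23 to 0.85. In the SART1 table, with its own controls, SEC24A stood at 0.96 and 0.98 and SRPRB at 0.88 and 0.65 with the 2 siRNAs.

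Such a rise in every knockdown could come from chance values of control libraries or from the control siRNA itself, and no biological explanation was tested. Chance is argued against, since the 2 tables have separate controls and independent lists would share 2.76 genes higher and 0.93 lower, against 32 and 6 seen. A candidate explanation is that the control siRNA lowers mRNAs holding the control word ATTACAA, so that they look higher in every knockdown. It assumes the same control siRNA in both tables, which the labels leave open, since the titles name the controls differently. With that explanation fits a mean z of 6.36 for the word in the FIBP and TMEM259 table, where the word ranked 1 as in the other table (5.63). Of the 32 genes 17 (53.1%) hold it, against 14.6% of 10750 genes and 17.8% at the same 3' UTR length. The other 15 genes lack it. The word and the genes were both picked for high fold changes with these same siRNAs, so an excess of holders follows from the choice. These shares are thus no separate support, and whether the word accounts for part of the set stays open. In the SART1 table, whose controls have the same name as those of FIBP and TMEM259, the word scored 2.45 (rank 452). TECPR2, which holds it, stood at -0.23 and -0.28 there, alone among the 32 genes. Every other gene of the set, with the word or without it, had positive log2 changes with both SART1 siRNAs. Among holders these ran from ACBD3 (1.14 and 0.97) to PABPC4 (0.13 and 0.07).

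Fold changes after SART1 knockdown followed transcript GC content across genes, with a rank correlation of -0.22 and -0.27 for the 2 siRNAs, so genes rich in GC were lower. The ratio of 0.81 between these does not test chance of 1 siRNA, since both are set against the same 2 controls, and that stays open. A GC bias between libraries stays open as well, since a difference between replicates in the same table correlated with GC at 0.25 in absolute value. A correlation of that size is not particular to SART1, though DDX39A siRNA 4 had the opposite sign (0.30, genes rich in GC higher). DDX39A siRNA 1 stood at 0.04, with 0.32 between control replicates in that table. Among the siRNAs of the other targets the lowest value was -0.06, with FIBP siRNA 6. No biological explanation was tested for this pattern.

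Low words also stood out for DDX39A siRNA 4 (AGTTAAA, z = -17.23), FIBP siRNA 6 (ATGACTG, -13.91), FIBP siRNA 7 (GCTAACA, -15.85), SART1 siRNA 4 (ACTAACA, -11.46) and TMEM259 siRNA 5 (CCATTCT, -10.0). They stood out less for DDX39A siRNA 1 (TTCGTCA, -5.67), SART1 siRNA 6 (AGCTACT, -6.09) and TMEM259 siRNA 6 (TCAAACA, -5.46, against -5.11 in shuffles). Genes with AGCTACT had the same median as those without it (0.01), and the word was also low with DDX39A siRNA 4 (-3.29) and SART1 siRNA 4 (-3.09), so a low word of SART1 siRNA 6 in a 3' UTR says little about that gene.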
